A study of Homo sapiens with 6 samples.

How the data were processed

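RNA was measured by sequencing in 6 libraries of PANC-1, a human cell line established from a pancreatic ductal carcinoma. Per the labels, 3 libraries came from cells with a non-targeting control hairpin (shNC) and 3 from cells with a short hairpin RNA against RRM2 (shRRM2). Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was taken with poly-T beads, and libraries were made with a directional NEB kit. The deposited table holds whole-number read counts per gene, with genes given as NCBI Gene IDs. Per the submitters' processing notes, fastp 0.23.4 and featureCounts were used with the hg38 build. The aligner, the annotation release, and the settings for strand and for reads that map to several places are not given in the sources used here. Reads shared between near-identical genes (mucin and CEACAM families, ribosomal protein genes and their processed copies, histones, ferritins) and reads of overlapping genes may therefore have been split or dropped in a way the table does not show.

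The columns of the table carry the prefix si for the RRM2 libraries where the labels have sh. Each column was matched to its sample by the gene name and the number, and no column was left over. The labels do not say whether the 3 libraries of a group came from separate cultures, nor how many hairpins were used. The p-values below therefore measure the spread between these libraries, which may be technical, and the comparison is between 1 control and 1 knockdown population as far as the labels tell. Of the 42902 Gene IDs of the table, 40120 were matched by ID to a symbol, a position and a biotype in the RefSeq annotation of GRCh38.p14. The unmatched IDs held 1.25% of the counts and stayed in library sizes and tests under their ID. Total counts per library ran from 16606947 to 23300433, so that a gene at 1 CPM rests on 16.6 to 23.3 counts in a library.

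Genes were kept with edgeR's filterByExpr at its default settings, which left 15866. Library sizes were scaled with TMM. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation, design with group alone, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Every adjusted p of a gene below is from this test unless an alternative is named. Fold changes are shRRM2 over shNC on the log2 scale with their standard error (SE), obtained as the size of the log2 fold change divided by the square root of the F statistic, and 95% intervals use the t distribution with the fit's degrees of freedom. Levels are CPM (counts scaled to a common library total) on the TMM-scaled library sizes, as mean ± SD over the 3 libraries of a group, computed from the deposited counts. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so none was used.

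Before the data were examined, 27 gene lists were fixed, 22 for pathways and cell states and 5 with markers of other cell types. A list was tested when at least 5 of its members passed the filter. The test was camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the tested lists, and it was repeated with the correlation estimated from the data. Members were also counted with p-values adjusted over the list alone. The rule for the genes named below was fixed at the same time. It takes 19 genes chosen for the study's subject, the 8 higher and the 8 lower genes with the largest log2 fold change among those past the threshold with a symbol, a mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list with the smallest adjusted p. A gene named outside this rule is marked as chosen after its values were seen. A list member below the filter is named with its counts. Some genes that the rule takes are not reported here, and counts over lists and over all genes include them.

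The alternatives planned at that time were RLE factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, an adjusted p of 0.01, edgeR's test against a minimum change (glmTreat), and for the lists an estimated correlation and fry. Leaving out the genes with either of 2 words in the 3′ UTR was added after the data were examined. The tests were checked on simulated counts with the real means, library sizes and dispersions, in 10 draws of 200 changed genes among 15866 for the comparison of shRRM2 with shNC. The number of draws was raised to 10 after a single draw gave a share of false calls above the limit set for it. They recovered 49.4% of the genes changed 1.25-fold, 71.0% of those changed 1.5-fold and 86.2% of those changed 2-fold, and 8.51% of the calls were false, above the nominal 5%. Far more genes passed in the data than were changed in a draw, which makes the adjusted threshold less strict there, so these shares may not carry over. In the same kind of simulation camera called 0 of 100 unchanged lists and called a list of 30 genes shifted by 0.4 on the log2 scale. The simulated genes were drawn independently of each other and the lists at random. The simulation therefore could not show how camera with the preset correlation behaves for lists whose genes vary together. For 3′ UTR sequences, the transcript with the longest 3′ UTR per gene was taken from a GENCODE annotation of GRCh38, and 12500 of 12676 tested protein-coding genes had one. After a first scan of 3′ UTR words, the match of genes to transcripts was widened to older symbols, which added MARCHF4 among others. The same pair of words was lowest before and after. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, word counts and figures.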

Results

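Gene expression was compared between PANC-1 cells with a short hairpin RNA against RRM2 and cells with a non-targeting hairpin, to look for genes that act downstream of RRM2. RRM2 encodes the small subunit of ribonucleotide reductase, the enzyme that makes the deoxynucleotides for DNA synthesis. There were 3 libraries in each group. Total counts were 17917227, 23300433 and 16606947 for shNC replicates 1 to 3 and 17442948, 19740706 and 17824619 for shRRM2 replicates 1 to 3. Mitochondrial transcripts took 6.12% ± 0.101 (SD, n = 3) of the counts in shNC and 5.96% ± 0.00855 (SD, n = 3) in shRRM2, and the 100 most abundant genes took 17.5% and 16.7%. The first principal component of log2 CPM held 65.9% of the variance and separated the groups. The libraries of 1 group differed more than sampling noise, with a chi-square per degree of freedom between 2.22 and 3.90 for pairs within a group and between 29.8 and 35.7 for pairs across groups. Chosen after its values were seen, CDKN2A, a tumour suppressor gene that is generally described as homozygously deleted in PANC-1, was counted at 270.1 to 292 CPM of the total in all 6 libraries. KRT19, a ductal keratin on the epithelial list, had 0 to 6 counts per library.

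RRM2 (Gene ID 6241, chromosome 2, 10122568 to 10211010, GRCh38) fell in the knockdown. Its counts were 3567, 4435 and 3342 in the shNC libraries and 716, 808 and 716 in the shRRM2 libraries, or 199.7 ± 6.38 CPM against 40.2 ± 0.607 CPM (SD, n = 3 each). The log2 fold change was −2.31 (SE 0.0443, adjusted p = 3.72e-29), which left 20.2% of the control level. RRM1 (Gene ID 6240), the large subunit of the same enzyme, rose by 0.20 on the log2 scale (SE 0.0315, adjusted p = 1.62e-06). RRM2B, the p53-inducible small subunit, was at 44.1 ± 1.67 CPM in shNC and 46.0 ± 1.93 CPM in shRRM2 (adjusted p = 0.415). Of the 18 genes of deoxynucleotide supply, 3 rose and 9 fell. TK1, the salvage kinase for thymidine, rose by 0.44, while DCTPP1 was lower at −0.39 and DUT, which removes dUTP, at −0.32. The list as a whole was not set apart from other genes (camera adjusted p = 0.311), and 3 members rose and 10 fell when adjusted over the list alone.

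**Figure D1:**
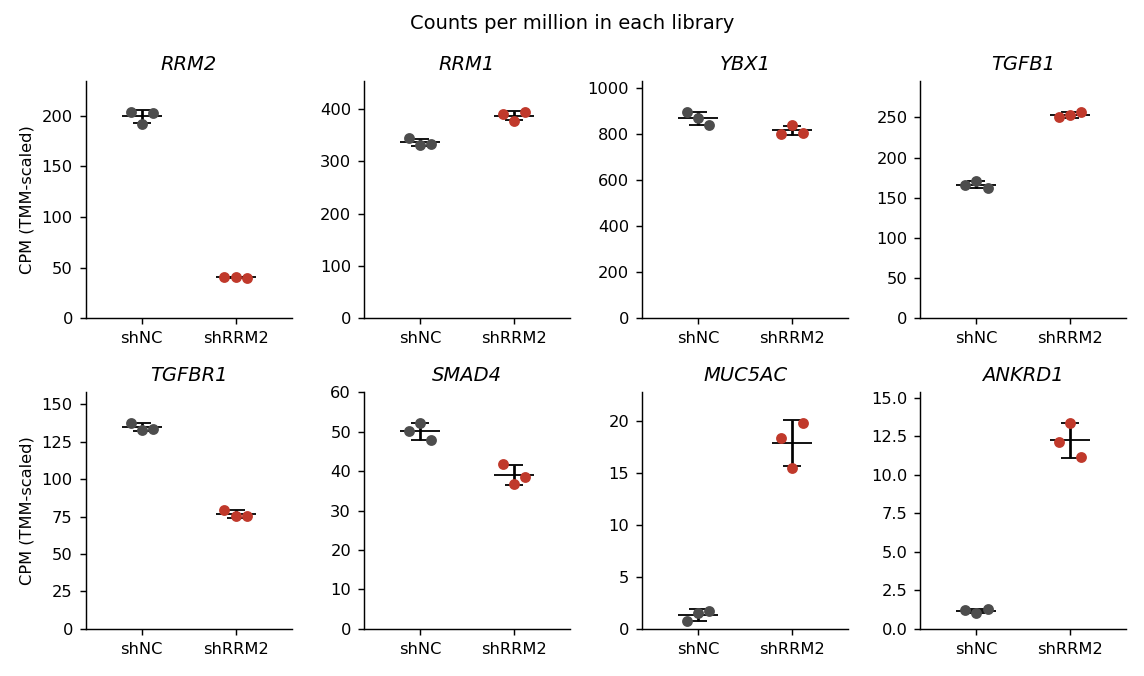
TMM-scaled CPM of 8 genes in each library (points), with the mean and SD of the 3 libraries of a group (bars); every axis starts at 0. RRM2 lay near 200 CPM in shNC and near 40 CPM in shRRM2, while YBX1 differed by a log2 fold change of −0.09.

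The knockdown went with small changes in a large part of the transcriptome and with large rises in a smaller set of genes. Of 15866 tested genes, 8261 passed the threshold, 4119 higher and 4142 lower in shRRM2, with a median size of 0.39 on the log2 scale. With a log2 fold change of at least 1, 1020 genes remained, 806 higher and 214 lower. The groups did not overlap in CPM for 57.8% of the tested genes, where chance gives 10%. In edgeR's test against a minimum log2 fold change of 1, 258 genes passed, 238 of them higher and 20 lower. With a stricter filter of 1 CPM in 3 libraries, 136 genes were lower by a log2 fold change of 1 or more.

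Among the genes with the largest rises was MUC5AC, a secreted gel-forming mucin of gastric and airway epithelium, which went from 1.34 ± 0.532 to 17.9 ± 2.23 CPM (log2 fold change 3.73, SE 0.183, adjusted p = 1.28e-17). ANKRD1, a target of the YAP coactivator, rose from 1.19 ± 0.130 to 12.2 ± 1.12 CPM (3.37, SE 0.182). CRYBG2 rose by 3.33, LBH by 2.99, CEACAM1, a cell adhesion molecule, by 2.72, MARCHF4, a membrane-bound ubiquitin ligase, by 2.68, DIO2, the deiodinase that activates thyroid hormone, by 2.67, and KCP by 2.40, all from means of 1.08 to 2.32 CPM in shNC. CEACAM1 and MUC5AC belong to families with similar sequences, so that shared reads leave some uncertainty in their counts.

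Among the genes with the largest falls other than RRM2, MAP2K6, a kinase that activates p38, fell from 15.5 ± 0.226 to 4.21 ± 0.272 CPM (−1.88, SE 0.131), and TMEM64, a membrane protein, was lower at −1.37 (SE 0.0957). GABBR1, a subunit of the GABA-B receptor, was lower at −1.48. The noncoding genes LOC112268235 and LINC00641 were lower at −1.61 and −1.52, and LOC105375957 fell from 10.6 ± 2.33 to 2.63 ± 0.222 CPM.

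**Figure D2:**
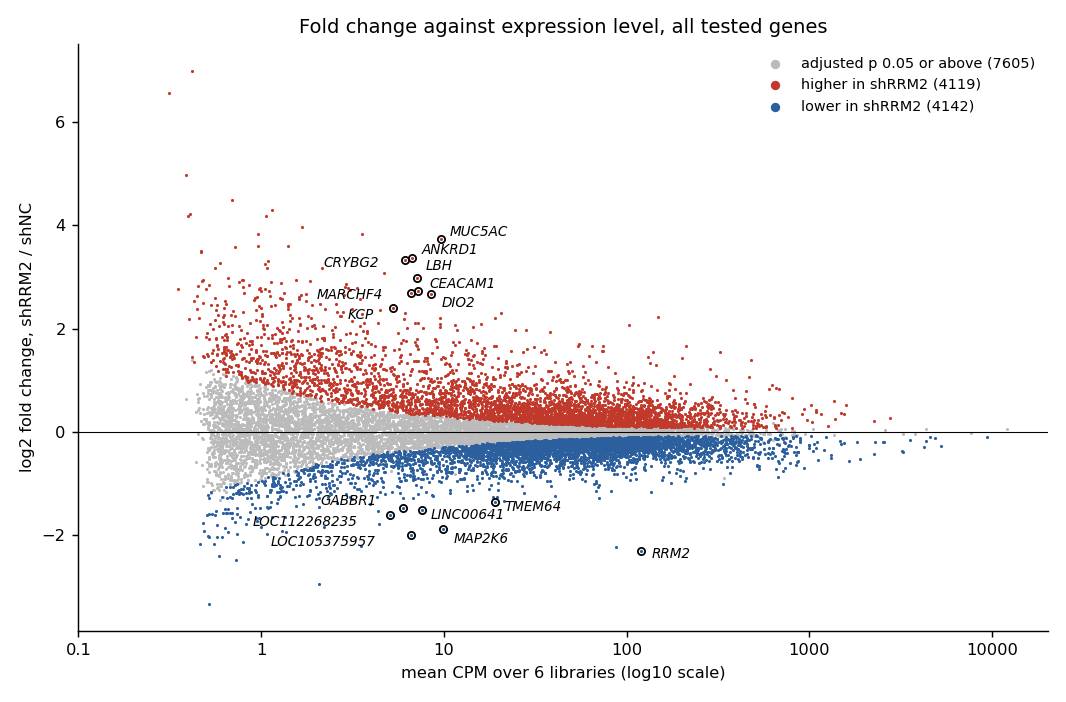
Log2 fold change (shRRM2 over shNC) against the mean CPM of the 6 libraries on a log10 axis, 1 point per tested gene; coloured points passed an adjusted p of 0.05, and circles mark the largest changes named in the text. RRM2 lies at −2.31.

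The study's title links RRM2 to YBX1 and to the TGF-beta pathway. YBX1, a DNA- and RNA-binding protein, was at 869 ± 27.9 CPM in shNC and 816 ± 21.3 CPM in shRRM2, a log2 fold change of −0.09 (SE 0.0294, adjusted p = 0.0104). This small difference no longer passed with library size alone (−0.05, adjusted p = 0.102) or without shNC replicate 1 (−0.07, adjusted p = 0.0664), shRRM2 replicate 1 (−0.08, adjusted p = 0.0657) or shRRM2 replicate 3 (−0.07, adjusted p = 0.0711).

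The components of the TGF-beta pathway moved in both directions. Of 27 measured ligands, receptors, SMADs, SMAD regulators and latency proteins, 13 rose and 8 fell (14 and 8 adjusted over the list alone). The type I receptor TGFBR1 fell from 135 ± 2.60 to 76.6 ± 2.51 CPM (log2 fold change −0.81, SE 0.0430, adjusted p = 4.80e-17), and the signal transducers SMAD2 and SMAD4 were lower at −0.46 (SE 0.0406) and −0.36 (SE 0.0631). The ligands TGFB1 and TGFB2 rose by 0.60 (SE 0.0347) and 0.93 (adjusted p = 1.29e-09), the type II receptor TGFBR2 by 0.45 (SE 0.0445), SMAD3 by 0.41 (SE 0.0564), and the latency proteins LTBP3 and LTBP2 by 0.51 and 2.00. The inhibitory SMAD7 was at 30.9 ± 3.55 and 33.9 ± 1.98 CPM (log2 fold change 0.13, adjusted p = 0.177). It passed only without shNC replicate 2 (0.21, adjusted p = 0.0457). The list did not pass camera (adjusted p = 0.135). With fry it passed upward (adjusted p = 0.00086), but fry, unlike camera, does not compare the members with other genes. Fry called 15 of the 22 tested lists, so its result does not set this list apart from other genes. The list also passed upward with camera without genes holding either of 2 words in the 3′ UTR (camera adjusted p = 0.00314). This last setting was chosen after the data were seen and favours a rise by construction, since the words were picked for low fold changes. It leaves out 6 of the 27, among them TGFBR1, SMAD2, SMAD4 and TGFBR2. Of these 6, 4 fell, among them TGFBR1, SMAD2 and SMAD4, against 4 of the 21 without either word. As the words were picked for low fold changes, this split is no separate test. Seed pairing by the hairpin stays open for these falls, so they may not follow from the loss of RRM2.

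Genes that TGF-beta induces were mostly higher in the knockdown. Of 29 measured targets, 19 rose and 6 fell (20 and 6 adjusted over the list alone; camera adjusted p = 9.66e-10, and 0.0327 with an estimated correlation). The matrix genes THBS1 and TGFBI rose by 1.66 and 1.47, and fibronectin (FN1) from 47.1 ± 3.66 to 112 ± 3.26 CPM. CCN1 rose by 1.08. Among the members that fell, chosen after their values were seen, were ID1 at −0.80 and ID3 at −0.66, which are best known as targets of BMP signalling. Of the 32 genes on this list, 17 also stand on another of the lists.

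**Figure D3:**
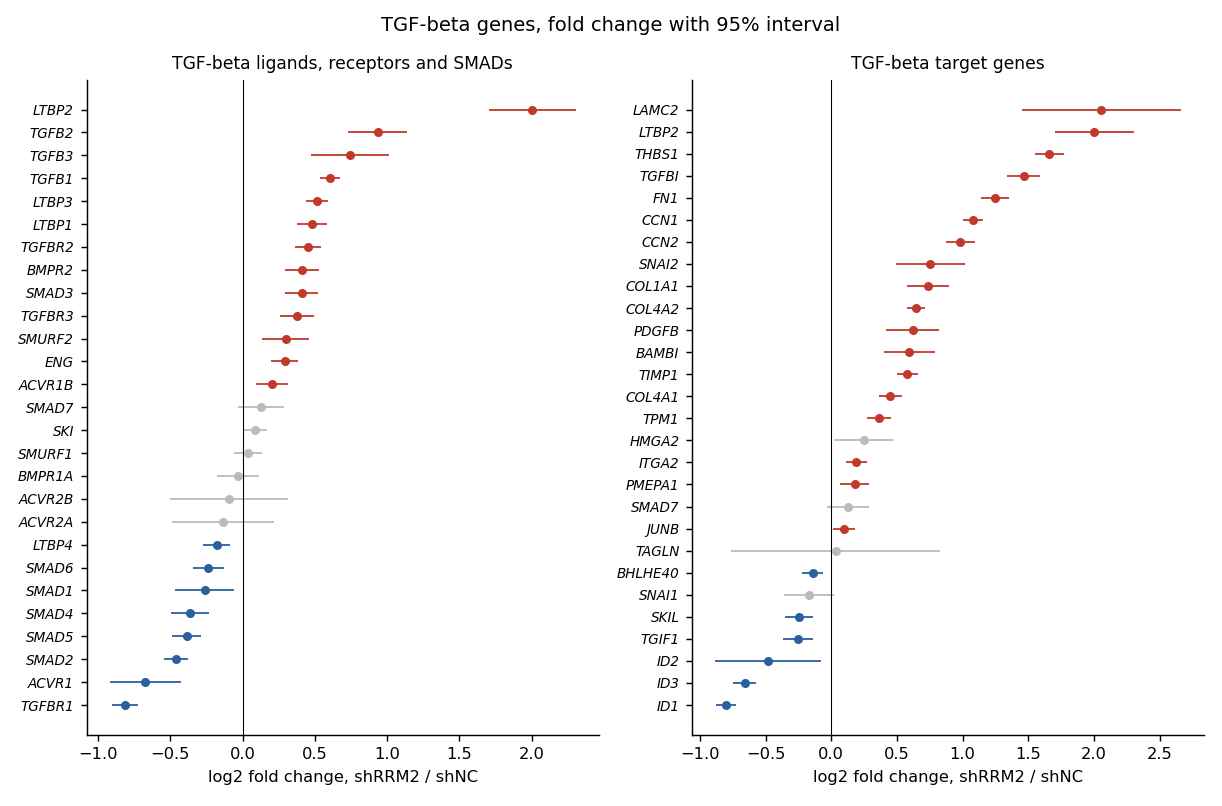
Log2 fold change (shRRM2 over shNC) of the measured TGF-beta pathway components (left) and 28 of the 29 measured target genes (right), with 95% intervals; coloured points passed an adjusted p of 0.05 (red higher, blue lower) and grey points did not. Components run from −0.81 for TGFBR1 to 2.00 for LTBP2, and targets such as THBS1 and TGFBI lie to the right, at 1.66 and 1.47.

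The genes of the extracellular matrix and its receptors had the smallest camera p of the fixed lists. Of 34 measured, 30 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 2.72e-20, and 0.0327 with an estimated correlation), and the median was 0.64. ITGB4, the integrin subunit of hemidesmosomes, rose by 1.21 (adjusted p = 2.15e-24), while ITGA3 was lower at −0.89 (adjusted p = 2.51e-20). Chosen after their values were seen, TNC, COL17A1 and LAMA4 rose by 3.28, 3.17 and 2.62, all from under 1 CPM in shNC. The 10 fibroblast markers were mostly below the filter, but the 3 that passed it were higher in shRRM2, PDGFRB by 1.65, COL1A1 by 0.73 and FAP by 2.78, also adjusted over the list alone. Without shNC replicate 1, 2 or 3, 5 of these markers were measured and the list passed upward (camera adjusted p = 0.00158, 0.00278 and 0.00241), with 4 of 5 higher. The filter asks for fewer libraries when a group is smaller, which let in COL3A1 and THY1. COL3A1 had 3, 2 and 0 counts in shNC and 15, 9 and 11 in shRRM2, and THY1 4, 10 and 8 against 8, 14 and 11. They entered through the group where they were higher, so these calls are no added support for a rise. DCN, LUM and COL1A2, abundant transcripts of fibroblasts, had totals of 8, 13 and 7 counts over all 6 libraries. Of 4 measured endothelial markers, ESAM, VWF and CDH5 rose by 0.76, 2.45 and 1.44, also adjusted over the list alone, and EGFL7 was at 0.03 (adjusted p = 0.669). The other 6 of the 10 endothelial markers were below the filter, among them KDR, PECAM1 and TEK with totals of 0, 17 and 21 counts over all 6 libraries. The single measured immune marker, CD68, also a lysosomal protein, rose by 1.67. The hepatocyte gene TF was at −0.08 (adjusted p = 0.905), and no acinar or endocrine marker of the pancreas passed the filter.

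Markers of both the epithelial and the mesenchymal state rose. Of 21 measured mesenchymal markers, 13 rose and 0 fell (13 and 1 adjusted over the list alone; camera adjusted p = 9.83e-05, and adjusted p = 0.0584 with an estimated correlation). FN1, described above, and ITGA5, AXL and LOX rose, the last 3 by 0.67, 0.45 and 0.85. CDH2 (N-cadherin) rose by 0.28 (SE 0.0571), VIM (vimentin) by 0.12 (SE 0.0292) and SNAI2 by 0.76 (SE 0.131). SNAI1 was at −0.17 (adjusted p = 0.132) and ZEB1 at 0.06 (adjusted p = 0.437). Of 20 measured epithelial markers, 13 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 4.86e-05, and 0.0394 with an estimated correlation). The keratins KRT8 and KRT18 rose by 0.60 and 0.45, the tight junction protein CLDN1 by 1.55 and the desmosomal DSP by 0.38. CDH1 (E-cadherin) rose by 1.43 (SE 0.318, adjusted p = 0.00028) but stood at only 0.860 ± 0.171 CPM in shNC and 2.36 ± 0.526 CPM in shRRM2. The epithelial regulators ESRP1, GRHL2 and OVOL1 had 0 counts in every library.

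The measured genes induced by interferon rose as a group. Of 28 measured, 22 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 0.76 (camera adjusted p = 4.56e-10, and 0.0327 with an estimated correlation). IFIT2 rose by 1.77, SAMD9L by 1.48, SAMD9 by 1.16 and the RNA sensor OAS1 by 0.77. The other 10 of the 38 genes on the list were below the filter. Among them CXCL10, RSAD2 and OAS2 had 1, 3 and 6 counts in total over all 6 libraries, and IFI27 had 58. Among 19 measured NF-kB and cytokine genes, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00358, and adjusted p = 0.0653 with an estimated correlation). The cytokine IL6 rose by 1.68, NFKBIZ by 1.30, the feedback inhibitor TNFAIP3 by 0.88 and IL32 by 0.36, while NFKBIA, chosen after its value was seen, was lower at −0.33. Of 18 measured immediate early genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.60e-06, and 0.0327 with an estimated correlation). FOSB rose by 2.04 and the MAP kinase phosphatases DUSP5 and DUSP4 by 1.57 and 0.79, and the member that fell was MYC, at −0.80 (adjusted p = 3.55e-20). All 22 YAP targets passed the threshold, 16 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.0002, and adjusted p = 0.0653 with an estimated correlation), with ANKRD1, CCN1, CCN2 and AMOTL2 at 3.37, 1.08, 0.98 and 0.52.

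**Figure D4:**
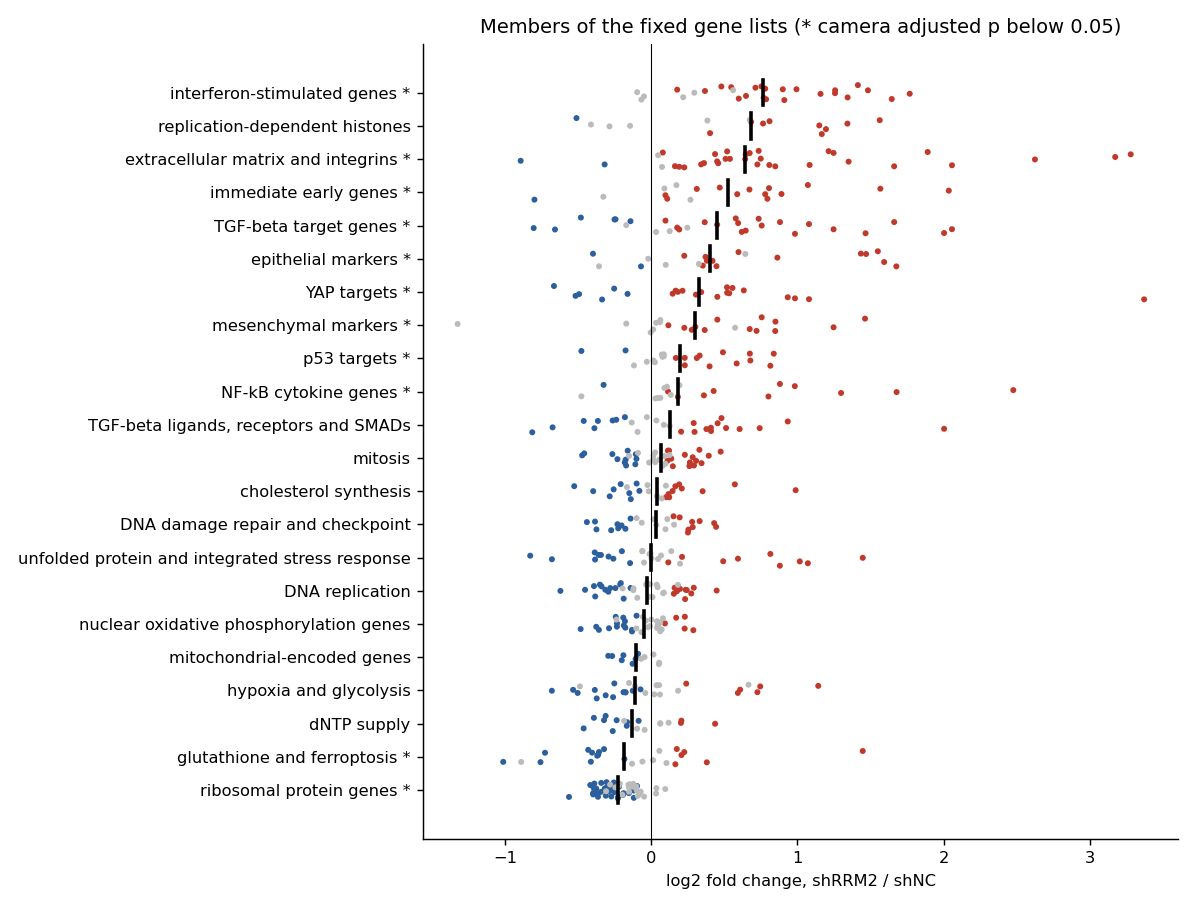
Log2 fold change (shRRM2 over shNC) of every measured member (points) of the 22 tested gene lists, with the median of the list (black bar); red and blue points passed an adjusted p of 0.05 and grey points did not, and the vertical scatter within a row has no meaning. Lists with a star passed camera, with medians from −0.23 for ribosomal protein genes to 0.76 for interferon-stimulated genes.

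The replication and division genes split into members that rose and members that fell. Of 39 DNA replication genes, 11 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 0.316). POLA1, the catalytic subunit of DNA polymerase alpha, was lower at −0.62, MCM3 at −0.39 and MCM6 at −0.38, while the licensing factor CDT1 rose by 0.45. Of 38 mitotic genes, 15 rose and 11 fell (16 and 12 adjusted over the list alone; camera adjusted p = 0.638), with PLK1 at −0.47, CDC20 at −0.46 and MKI67 at −0.27 against KIF2C at 0.39. Of 25 genes of DNA repair and checkpoints, 9 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.929), with MSH6 at −0.44 and UNG at −0.38 against EXO1 at 0.44 and FANCI at 0.28. Targets of p53 rose more often than they fell, 12 against 2 of 22 measured and also adjusted over the list alone (camera adjusted p = 0.0402, and adjusted p = 0.272 with an estimated correlation). TP53I3 rose by 0.84, SESN2 by 0.81 and CDKN1A (p21) by 0.40, while CCNG1 was lower at −0.48. Without shNC replicate 3 the p53 list did not pass (adjusted p = 0.0681). Of the 15 measured replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that the library protocol selects, 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.135). H3C2, H3C10, H1-2 and H2BC12 rose by 1.56, 1.17, 0.76 and 0.40.

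Genes of redox and iron metabolism fell more often than they rose. Of 23 measured genes of glutathione metabolism and ferroptosis, 6 rose and 11 fell (6 and 12 adjusted over the list alone; camera adjusted p = 0.000397, and adjusted p = 0.0516 with an estimated correlation). Among the members that were lower were thioredoxin reductase TXNRD1 at −0.76, the transferrin receptor TFRC at −0.73 and the ferritin light chain FTL at −0.40. Ribosomal protein genes shifted together by a small amount. Of 59, 0 rose and 38 fell (0 and 40 adjusted over the list alone; camera adjusted p = 5.30e-08, and adjusted p = 0.476 with an estimated correlation), with a median of −0.23 and RPL14, RPL35, RPL7A and RPL5 at −0.56, −0.42, −0.40 and −0.38. Without shRRM2 replicate 2, in which RPL12 (chosen after its values were seen) stood at 115.9 CPM against 66.6 to 87.4 in the other libraries, 56 of the 59 fell.

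The other metabolic lists did not pass camera. Of 13 genes of the mitochondrial genome, 0 rose and 8 fell (2 and 8 adjusted over the list alone; adjusted p = 0.0980), with ATP6, CYTB, ND5 and ATP8 at −0.27, −0.20, −0.19 and −0.29. Of 36 nuclear genes of oxidative phosphorylation, 5 rose and 14 fell, also adjusted over the list alone (adjusted p = 0.163), among them NDUFS1 at −0.38, ATP5MC1 at −0.48, CYC1 at −0.29 and ATP5F1B at −0.24. Both lists passed without shRRM2 replicate 2 (adjusted p = 0.0258 and 0.0297). Of 29 genes of hypoxia and glycolysis, 6 rose and 13 fell, also adjusted over the list alone (adjusted p = 0.251), with the lactate transporter SLC16A3 at −0.68 and LDHA at −0.53 against the hypoxia-induced ADM at 1.14 and P4HA1 at 0.73. The median of this list was −0.11 and its mean 0.01. Of 25 genes of cholesterol synthesis, 10 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.929), with HMGCS1 at −0.26, MVK at 0.57 and ACAT2 at 0.35. Of 29 genes of the unfolded protein and integrated stress responses, 9 rose and 10 fell, also adjusted over the list alone (adjusted p = 0.929), with DDIT4 at −0.68, SLC7A5 at −0.38, HSPA5 at −0.34 and NUPR1 at 1.02. Camera gave the last 2 lists a downward direction although their means were 0.03 and 0.10.

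In total 11 of the 22 tested lists passed camera, 9 upward and 2 downward, and 5 of them passed with an estimated correlation. Camera with the preset correlation also called up to 9 lists when the 6 libraries were split into groups that mixed shNC and shRRM2. Such groups still differ by a part of the difference between shNC and shRRM2, so this number does not count false calls. All 118 named genes past the threshold had every shRRM2 library on 1 side of every shNC library. For the genes named for the largest changes, the rule itself required this. List members were taken by the smallest adjusted p, which favours it. The count is therefore no separate check of the named genes as a whole.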

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

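The alternatives were planned before the data were examined, except leaving out the genes with either of 2 words in the 3′ UTR, which was chosen after seeing the data. The count of genes past the threshold was 7449 with DESeq2, 6672 at an adjusted p of 0.01, 6969 without the genes with either word and between 8088 and 8282 with RLE factors, library size alone, no filter, 1 CPM in 3 libraries, limma-voom and the replicate block, and leaving out 1 library gave 7490 to 7975 (3754 to 4031 higher and 3736 to 3944 lower). No gene past the threshold was called in the opposite direction in any of these refits. The largest shift of the median log2 fold change by scaling was 0.04, with library size alone, which put 56.2% of the calls on the higher side against 49.9%. RRM2 ranged from −2.34 to −2.29 when 1 library was left out. The count with a log2 fold change of at least 1 moved to 258 with glmTreat, whose null bound is stricter by construction, and was 1042 to 1111 with 1 library left out (821 to 884 higher and 207 to 251 lower). With 1 CPM in 3 libraries the lower part went to 136, as fewer genes were tested (14642). The count of lists moved to 5 with an estimated correlation, was 15 with fry, 12 without the genes with either word, and 11 to 13 with 1 library left out, where fibroblast markers entered without each shNC library. Without the genes with either word, TGF-beta components passed upward (camera adjusted p = 0.00314), which is no support for a rise, since the words were picked for low fold changes. Of 1702 values of the 123 named genes other than RRM2, 1697 kept their side of the threshold, and the exceptions were 4 of YBX1 and 1 of SMAD7, whose cause was not tested. No gene past the threshold in either fit changed direction. Direction was not counted for genes past it in neither, such as TF, at 0.21 without shNC replicate 1 and 0.28 without shRRM2 replicate 3. Of 286 values of the lists, 272 kept their side of the threshold, 7 lost and 7 gained the call, and no call reversed. Lists past it in neither test could change direction, as the unfolded protein and integrated stress responses did, downward with camera and upward with fry. Samples with the same number did not deviate together (correlations across genes −0.00677, −0.00339 and −0.0208), so the numbers were not taken to pair the samples. With the replicate block 8244 genes passed, 8144 of them shared, and 11 lists. At this depth, genes changed 1.5-fold were recovered in 71.0% of simulated cases.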

Other observations

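The gene groups in the first part, all tests on the 3′ UTR words and on CDKN2A, and the test of ribosomal protein genes with 1 library left out were chosen after the values were seen. Mucin genes rose beyond MUC5AC, which prompted this group. Of 9 measured, 7 rose and 0 fell (camera adjusted p = 1.09e-08 over 9 added groups, and 0.0161 with an estimated correlation), and of the 8 other than MUC5AC 6 rose and 0 fell (4.05e-06, and 0.0337 with an estimated correlation). MUC13, a membrane mucin, rose from 25.5 ± 1.31 to 83.6 ± 4.91 CPM (SD, n = 3), MUC1 from 467 ± 43.1 to 841 ± 4.98 CPM, and MUC2 from 2.33 ± 0.293 to 6.92 ± 0.937 CPM. Of 12 keratins 6 rose and 2 fell (4.08e-05, and adjusted p = 0.0983 with an estimated correlation), with KRT17 going from 35.7 ± 1.27 to 113 ± 2.31 CPM and KRT16 at a log2 fold change of 1.89. Similar sequences within both families leave some uncertainty in these counts.

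Lysosomal genes rose in 25 of 36 cases and fell in 5 (camera adjusted p = 7.89e-09, and 0.0161 with an estimated correlation). GRN, CTSB and CTSD rose by 0.83, 0.82 and 0.53, and GPNMB, a lysosomal glycoprotein, from 15.9 ± 0.864 to 60.7 ± 1.51 CPM. Of 23 genes of the actin cytoskeleton and its contractile apparatus, 19 rose and 0 fell (4.23e-13, and 0.0487 with an estimated correlation), with TPM4 at 1.39 and MYL9 at 1.55. Class I antigen presentation had 9 of 17 genes higher and 2 lower (0.0318, and adjusted p = 0.312 with an estimated correlation), among them B2M at 0.30. Metalloproteinases and their inhibitors had 6 of 11 higher and 0 lower (0.00579, and adjusted p = 0.0823 with an estimated correlation). Tubulins, aminoacyl-tRNA synthetases and proteasome subunits did not pass (camera adjusted p = 0.248, 0.174 and 0.890). The 6 groups that passed also did so, upward, with RLE factors and with library size alone.

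Among 15767 words of 7 bases scored against the fold changes of 10689 genes by their 3′ UTR, after regression on length, GC content and expression, TCTAATG (score −6.64) and CTAATGA (−6.55) were lowest, against −4.81 for the lowest in 100 permutations. The highest score, 5.33 for CACCCCT, was also larger in size than −4.81. The permutations may therefore give too narrow a range, and they do not by themselves set the 2 words apart. Genes with both words joined (351, among them MAP2K6 and TMEM64, which fell, and DIO2, which rose) had a mean log2 fold change of −0.16 (SE 0.0248) against 0.05 (SE 0.00460) in the 7660 without the 6 bases that the 2 words share, a difference of −0.21 (SE 0.0253). These means were taken without the regression, so 3′ UTR length, GC content and expression may add to their difference. After the regression, genes with a word differed from all others by −0.082 for TCTAATG and −0.083 for CTAATGA. Base composition alone is argued against, since the median score of other words with the same bases as each was −0.188 (SD 1.00) and −0.178 (SD 0.966). The lowest of these other words scored −3.80 (CTAATGT) and −4.83 (ACTAATG), and both hold the shared 6 bases. That they scored above the 2 words was fixed by picking the lowest words, and carries no weight of its own. The 3′ UTR score of TCTAATG does not rest on genes that also hold it in their coding sequence. It was −6.59 in the 10174 genes lacking it there, after regression on coding length and GC content too. That test left out few of the 10689 genes, so it cannot decide whether the composition of the whole transcript plays a part. It replaced an undecided one, in which the words scored −3.44 (TCTAATG) and −2.38 (CTAATGA) in coding sequences. Seed pairing by the hairpin, whose sequence is not given in the sources used here, stays open. TCTAATG lies in RRM2's coding exons 7 and 9 (chromosome 2, 10127194 to 10127200 and 10129091 to 10129097, GRCh38), followed by A in both, so that the joined 8 bases (TCTAATGA) occur 2 times. Of the scored words of 7 bases 18.4% occur in that transcript, and of 44619 words of 8 bases 6.67% occur there and 0.345% at 2 or more places, but pairing needs no second place. A changed microRNA stays open as untested. The 2 words leave most falls unaccounted for, with an excess of 257 among 3484 lower genes (7.38%) over the share in genes without the 6 bases. This excess too was counted without the regression.

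CDKN2A was counted at 4486 to 6771 reads per library, while KRT19 stood at no more than 0.344 CPM, EPCAM at no more than 0.811 CPM and KRT7 at 675 to 714 CPM. Reads of neighbouring or antisense genes are argued against as the source, since the highest count of CDKN2B, CDKN2B-AS1 or MTAP in any library was 20.7% of that of CDKN2A. No genotype or reference profile of a line was used here, so whether the cells of both groups were of another line, or of a subline that kept the locus, stays open as untested. CDKN2A itself did not pass between the groups (log2 fold change −0.03, adjusted p = 0.492).

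For the small fall of ribosomal protein genes, transcript length, GC content and expression level are argued against as the whole cause, since the median was −0.16 (SE 0.0201) after regression on them, against −0.23 (SE 0.0208) before. A single library carrying the fall is argued against, since the median nearest 0 with 1 library left out was −0.19 (SE 0.0245, without shRRM2 replicate 3) and the lowest −0.29 (without shRRM2 replicate 2), and scaling as well, since it was −0.19 with library size alone. Processed copies that share reads with these genes, and an effect of the knockdown, stay open as untested. The SEs of these medians treat the 59 genes as independent, although their estimated correlation was 0.627, so they are too small for the spread between libraries. The arguments above therefore concern the shift measured in these libraries, not whether it exceeds that spread. With the correlation estimated from the data the list did not pass (camera adjusted p = 0.476), so that a shift these genes share between libraries for other reasons stays open too. FTH1, another gene with many copies, stood at 128.6 CPM in shRRM2 replicate 2 against 277 and 313 in the other shRRM2 libraries.

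With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 8261 genes past the threshold and the highest of the others 0 by edgeR, with 90 to 184 genes at an unadjusted p under 0.05 in those others. Other tools were not run on the splits. For a log2 fold change of at least 1 the values were 1020 and 0. For the lists they were 11 and 9 with the preset correlation, and 5 and 0 with an estimated correlation. In each case 1 of the 10 splits, the real one, gave a result as large. Every other split mixed shNC and shRRM2 libraries, so that the difference between them counted as spread within each group. Few or no genes could pass there whatever the cause of that difference. The mixed groups also kept a part of it between them, which can move lists. The splits therefore cannot tell how many calls chance alone would give, and no conclusion is drawn from them.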
